A study of Arabidopsis thaliana with 4 samples.

How the data were processed

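Whole seedlings of Arabidopsis thaliana, ecotype Col-0, were sequenced in 4 RNA libraries, 1 for each combination of genotype and treatment. The genotypes were wild type (WT) and a line overexpressing the microRNA miR164 (miR164OE). Plants grew at 22 °C, and the heat-treated seedlings, 5 days old at the start, were kept at 35 °C for 5 days, per the labels. No age is recorded for the control seedlings in the sample data used here. Equal age at harvest is therefore not shown. RNA was extracted with Trizol and the libraries were made with a strand-specific Agilent SureSelect kit, per the labels' protocols.

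The authors deposited 1 table of FPKM values (fragment numbers divided by transcript length and by the number of mapped fragments) for 32823 rows, each row carrying a locus code. Base calling with bcl2fastq 2.1.7, alignment and quantification tools named TopHat and Cufflinks, and the genome build TAIR10 are listed per the submitters' processing notes. Versions of TopHat and Cufflinks, the strand setting and the annotation are not given in the sources used here. The library depth is not stated either. FPKM divides by transcript length, so 1 fragment is worth many FPKM units on a short row, and Cufflinks estimates on rows of under 300 bases are the least certain.

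Row codes were matched to a TAIR10.1 annotation. Of the rows, 32538 had a gene of the same code with exons there, and 22305 of 22307 single-gene loci had the same start and end. Exon overlaps between genes on opposite strands, exon lengths and gene types came from that annotation. No locus code was repeated, so no rows had to be summed. Every column of values belonged to 1 of the 4 samples.

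Differences were computed as log2(FPKM + 1) in 1 library minus log2(FPKM + 1) in the other, which understates the fold of low rows. Rows with a mean of at least 1 FPKM over the 4 libraries were counted, and a row was called higher or lower at a difference of at least 1 on the log2 scale, or 2-fold. With 1 library per group there is no estimate of the spread between plants, no p-value was computed, and each difference compares libraries. The heat differences of the genotypes were subtracted from each other (miR164OE minus WT) by the same rule.

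In all, 30 gene lists with 462 distinct genes were written before the data were examined, as were the rule of size, the row minimum, the pseudocount and the rule for named genes. A list was described where at least 3 coding members passed the row minimum, and its median difference was placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins. A list outside the central 95% (below the 2.5th or above the 97.5th percentile) was reported as standing apart in these libraries. The rule for named genes took every miR164 precursor and NAC target, the 6 highest and 6 lowest differences of each comparison among rows with a symbol and a mean of at least 5 FPKM, up to 4 members per described list with the largest absolute difference, and the 5 highest and 5 lowest rows for the difference of heat responses. Genes named from a row on the other strand were chosen after their values were seen.

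Because most of the FPKM lay on rows opposite another gene, a second readout was added after the values were seen. Inner rows were rows with at least 90% of their exon bases inside 1 coding gene on the other strand, no overlap on their own strand, fewer bases than that gene, at least 300 bases and a mean of at least 20 FPKM. A wider set took rows overlapping 1 coding gene on the other strand by at least 100 bases, with at least 40 estimated fragments over the 4 libraries. That minimum was taken after minimums of 20, 40 and 80 had been compared. The values listed for such rows are named by the coding gene opposite to them, although 583 of the 1188 rows of the wider set (49.1%) belong to other coding genes.

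Depth, meaning here the number of fragments that FPKM was divided by, was estimated from the FPKM worth of 1 fragment. This worth was, in each library, the mode of FPKM times exon length. The mode was taken over rows of 800 to 2500 bases with no overlapping gene and under 6 FPKM. The mode is approximate. Counting error was simulated 100 times from it over rows of at least 300 bases, by drawing both libraries of a comparison from their common value. For the difference of heat responses, the 4 libraries were drawn from an additive fit of genotype and heat on the log2 scale. The simulation covers counting error only.

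The rule of size was tested on simulated data for WT heat against WT control over 9888 rows. Among rows with a mean of at least 20 FPKM, 100% of the 50 rows raised 4-fold and 100% of the 50 raised 8-fold were found, and 2.47% of unchanged rows passed. Among rows under 20 FPKM, 86% of those raised 4-fold and 96% of those raised 8-fold were found, and 31.4% of unchanged rows passed. For the list percentiles, 26 of 400 lists with no shift (6.5%) fell outside the central 95%, and a list with a large shift reached the 100th percentile. These values were drawn independently for each row. The check therefore covers neither lists whose genes vary together nor small shifts.

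Alternatives were a pseudocount of 0.1 or 5, no row minimum, a mean of at least 5 FPKM, rescaling by median ratios, and nuclear rows rescaled to a sum of 1000000. Rows without a gene on the other strand, a mean of at least 20 FPKM, other limits for inner and wider rows and another worth of 1 fragment were added after the values were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.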

Results

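Transcript abundance was measured in 4 RNA libraries from Arabidopsis seedlings, 1 each from WT control, WT heat, miR164OE control and miR164OE heat. miR164 is a microRNA that directs cleavage of transcripts of several NAC transcription factors. The labels state that the transcriptomes of both genotypes were examined with and without heat. There were no replicates, so every difference below is between single libraries. Summed FPKM was 1901841 in WT control, 1136254 in WT heat, 1983185 in miR164OE control and 1065963 in miR164OE heat. The 10 highest rows held 43.0% and 44.4% of it in the WT and miR164OE control libraries, and 27.2% and 25.2% in the WT and miR164OE heat libraries. Of all rows, 68.6%, 64.8%, 69.2% and 56.2% were listed at 0 in WT control, WT heat, miR164OE control and miR164OE heat. A fragment on a transcript of 1 kb was worth about 2.02, 1.77, 2.18 and 1.24 FPKM in the same order. By this estimate the number of fragments that FPKM was divided by was largest in miR164OE heat. Which fragments entered that number is not stated, so the depth of sequencing is not shown. Rows encoded in the mitochondrion summed to 1172 FPKM in WT control and 28927 in WT heat, and to 1350 and 34963 in miR164OE control and heat. Plastid rows summed to 2965 and 2149 FPKM in WT, and to 3772 and 1868 in miR164OE.

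Most of the signal lay on rows that overlap another gene on the opposite strand. Such rows made up 27.0% of the annotated rows but 95.1% of summed FPKM in WT control, 89.0% in WT heat, 95.4% in miR164OE control and 87.8% in miR164OE heat. Of the 100 highest rows, 96 lay opposite a gene. Among 664 rows lying inside a coding gene on the other strand with a mean of at least 1 FPKM, 566 (85.2%) were higher than the row of that coding gene. Median levels were 163 FPKM for the inner rows and 1.69 FPKM for the rows of the coding genes around them. Values are therefore given below as listed for a gene's own row, and for some genes also for a row on the strand opposite to the gene. Over 103 genes with an own row of at least 5 FPKM, the heat differences of own and inner row correlated across genes with Pearson's r = 0.16 in WT and 0.32 in miR164OE. Over 64 genes with an own row of at least 20 FPKM it was 0.10 and 0.36, and over 37 with at least 50 FPKM 0.09 and 0.01. For the 61 inner rows with a mean of at least 1000 FPKM, the own rows of the genes around them summed to 0.233% of the inner rows in WT control and 0.486% in WT heat, and to 0.225% and 0.593% in miR164OE. This share was thus 2.08 and 2.63 times as high after heat in WT and miR164OE. Between the controls it was 0.966 times as high in miR164OE as in WT by the sums, and 0.741 times by the median over the rows. Between the heat libraries it was 1.22 and 1.38 times as high in miR164OE. The share stands beside every heat or genotype difference of own rows given below. Genes are not independent replicates, and the own rows are not shown to track the abundance of the genes they are named for.

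**Figure D1:**
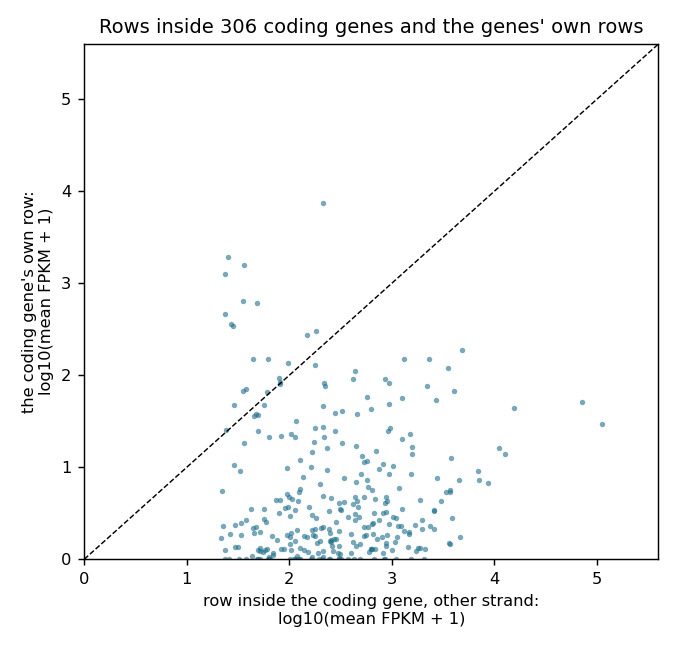
Each point is 1 of 306 coding genes with a row inside it on the other strand. The x axis is log10 of the mean FPKM plus 1 of the inner row, the y axis the same for the gene's own row, over the 4 libraries, and the dashed line marks equality. Most points lie below the line.

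The overexpressed microRNA could not be followed in these values. MIR164A, MIR164B and MIR164C, precursor genes of 113, 153 and 102 bases, were listed at 0 in all 4 libraries, so the genotype labels were not checked by them. Of the NAC genes that miR164 targets, CUC1, CUC2, NAC080 and NAC100 were also listed at 0 in all 4. ORE1, a regulator of leaf senescence (chromosome 5, 15858398 to 15859911, TAIR10), was listed at 2.73 FPKM in WT control and 11.2 in WT heat, and at 0 and 1.48 in miR164OE control and heat. These values correspond to about 1.77, 8.33, 0 and 1.56 fragments. NAC1, known for its part in lateral root development (chromosome 1, 20946571 to 20949281), was listed at 5.43 and 38.3 FPKM in WT control and heat and at 11.005 and 27.2 in miR164OE. A row opposite NAC1 had 35.9 and 96.2 FPKM in WT and 49.2 and 65.7 in miR164OE.

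The comparison of WT heat with WT control asked what prolonged heat was accompanied by in wild type. Small heat shock proteins, chaperones that bind unfolding proteins, were higher after heat, with 12 of 16 measured rows at least 2-fold higher and none 2-fold lower (median 1.74, 99.9th percentile of random lists). Light-harvesting and photosystem genes were lower in 28 of 34 rows and higher in 2 (median -1.79, percentile 0). HSP17.6A-CI was listed at 0.891 FPKM in control and 26.0 after heat, and HSP17.6II, HSP17.4 and HSP23.5 were listed at 0 in control and at 12.9, 11.2 and 7.66 after heat. The antenna genes LHCB1.4, LHCA1, LHCB1.3 and LHCB4.2 differed by -3.93, -3.33, -2.68 and -2.63 on the log2 scale, LHCA1 from 146 to 13.6 FPKM.

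Genes of the Calvin cycle, the pathway of carbon fixation, were lower in WT heat in 6 of 17 rows and higher in none (median -0.91, percentile 0.43). Within this list GAPA, RCA and RBCS2B differed by -1.74, -1.67 and -1.56, and CP12-2 was listed at 16.4 FPKM in control and 0 after heat. Glucosinolate synthesis was lower in 7 of 14 rows and higher in 2 (median -0.88, percentile 1.49). This list no longer stood apart with nuclear rows rescaled to a common sum (median -0.17, percentile 2.585, 3 of 11 rows higher and none lower) or with a mean of at least 5 FPKM (median -1.06, percentile 5.9, 5 rows). CYP79F2 and MAM1 differed by -1.62 and -1.60, BCAT4 was listed at 2.204 FPKM in control and 0 after heat (-0.51 for the row of IKU2 opposite it), and CYP83B1 went the other way with a difference of 1.87. The highest single rows were PUB21, a U-box ubiquitin ligase gene (chromosome 5, 14887429 to 14889151), listed at 0 and 367 FPKM, and LECRK56, a lectin receptor kinase gene lying next to a copy of the retrotransposon ONSEN (chromosome 3, 22064192 to 22065957), at 1.301 and 294 FPKM. The other 4 highest were the mitochondrial rows ORF143, ORF25, ORF111D and NAD4L, all listed at 0 in control. Lowest were U5.1b, MT1A, MIR156i, PLS and SCRL22, each listed at 0 in WT heat, and KLP, with 112 FPKM in control and 2.84 after heat. The first 3 of these are rows of 101, 138 and 197 bases, on which 1 fragment is worth many FPKM.

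Rows on the strand opposite to heat shock and photosystem genes were also compared in WT. The row opposite HSP17.4 (the gene at chromosome 3, 16984118 to 16984867) had 306 FPKM in control and 8610 after heat, and that opposite HSFB2B, a heat shock factor, 406 and 1646. Opposite the light-harvesting gene LHCB1.5 the values were 158697 and 72862 FPKM, opposite PSAG of photosystem I 171972 and 52342, and opposite PSAE1 164547 and 38249. The rows read for 5 photosystem genes were all at least 2-fold lower (median -1.72, percentile 1.09), and of those read for 7 genes of the heat shock and chaperone lists 4 were at least 2-fold higher and none lower (median 2.02, 99.985th percentile). Several of them are rows of other genes that overlap only in part. PSAH2 was read from ROPGEF11, with 174 of 2094 bases opposite it, HOP3 from PME1 (163 of 1851), ATJ2 from AT5G22050 (371 of 1834) and DREB2B from TBL32 (1086 of 2479), and the row for LHCB6 had 143 of 358 bases opposite it. Over rows with at least 50% of their bases opposite the gene, the median of 4 heat shock genes was 3.41 (percentile 99.895), and that of 3 photosystem genes was -1.72 and no longer stood apart (percentile 6.72). In all, 3126 of 10488 rows were at least 2-fold higher and 2280 at least 2-fold lower. With nuclear rows rescaled to a common sum, 79.0% instead of 57.8% of the 2-fold rows were higher and the median difference was 0.71 instead of 0. On that scale the photosystem median was -1.04 (percentile 0), with 18 of 33 rows lower, and the Calvin cycle median -0.21 (percentile 0.26), with 2 rows lower and 2 higher. The photosystem genes read from the opposite strand then had a median of -0.94 (percentile 1.165), with 2 of 5 lower. With a pseudocount of 0.1 or 5 the median of small heat shock proteins was 4.605 or 0.75, and with 5 those of the Calvin cycle and glucosinolate lists were -0.50 and -0.38. Over rows of at least 300 bases, the count of 2-fold rows was 2.24 times that expected from counting error alone, and 14.1 times among those with a mean of at least 20 FPKM.

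**Figure D2:**
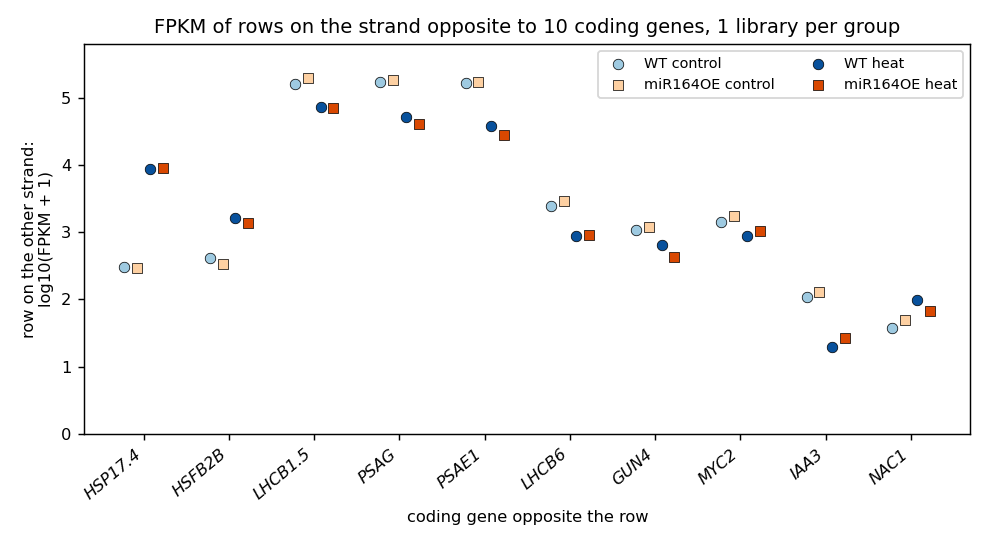
Points are log10 of the FPKM plus 1 of rows on the strand opposite to 10 coding genes, 1 point for each of the 4 libraries, on the y axis; the genes are on the x axis. The row opposite HSP17.4 has 8610 and 9026 FPKM in the heat libraries and 306 and 287 in the controls, while LHCB1.5, PSAG and PSAE1 are lower in the heat libraries.

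In miR164OE, heat was accompanied by higher values for chaperones of several classes. Small heat shock proteins were higher in 12 of 16 rows and lower in 1 (median 2.36, 100th percentile), and 19 of 21 rows of the HSP100, HSP90 and HSP70 chaperones and their partners were higher and 1 lower (median 2.57, 100th percentile). Genes of protein folding in the endoplasmic reticulum were higher in 9 of 15 rows and lower in none (median 1.54, percentile 99.06). The folding list no longer stood apart with a pseudocount of 0.1 (percentile 93.275), without a row minimum (median 0.90, percentile 90.61) or with a mean of at least 5 FPKM (percentile 90.625, 5 rows). Photosystem genes were lower in 18 of 34 rows and higher in 1 (median -1.05, percentile 0). HSP70-4, ROF2, ATJ2 and HSP90.2 were listed at 0 in miR164OE control and at 13.1, 9.46, 8.17 and 6.94 FPKM after heat. BIP1 and BIP2, HSP70 proteins of the endoplasmic reticulum, differed by 2.25 and 2.14, ERDJ3B was listed at 0 and 6.68 FPKM, and SDF2 at 0 and 4.27.

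Among small heat shock proteins in miR164OE, HSP22.0, HSP17.4 and HSP17.6C-CI were listed at 0 in control and at 21.2, 13.9 and 10.4 FPKM after heat, and HSP17.6II differed by 2.65. The antenna genes LHCB2.3, LHCB1.3, LHCB1.2 and LHCB4.2 differed by -2.49, -2.21, -1.83 and -1.80. Of the 6 highest rows, ORF25, ORF111D, ORF105B, ORF153A and ORF149 are mitochondrial and were listed at 0 in miR164OE control, as was U5.1b. Lowest were the plastid rows PSBK, RPS14 and PSAC, the small nuclear RNA U2.11, MLO3 and SEN1, a gene marked by senescence and darkness (chromosome 4, 16944878 to 16946266). All 6 were listed at 0 in miR164OE heat, SEN1 after 46.9 FPKM in control and MLO3 after 78.5.

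On the opposite strand the miR164OE values were 287 FPKM in control and 9026 after heat for HSP17.4, 338 and 1374 for HSFB2B, 199133 and 69274 for LHCB1.5, 182750 and 40225 for PSAG, and 173586 and 27964 for PSAE1. The 5 photosystem genes had a median of -2.18 (percentile 0.125) and the 7 heat shock and chaperone genes, 5 of them at least 2-fold higher and 1 lower, a median of 1.07 (percentile 99.71), which is the value of the PME1 row read for HOP3. Over rows with at least 50% of their bases opposite the gene, 4 heat shock genes had a median of 1.29 (percentile 98.84) and 3 photosystem genes one of -2.18 (percentile 1.825). Altogether 3406 rows were at least 2-fold higher and 1803 at least 2-fold lower. Over rows of at least 300 bases, the count of 2-fold rows was 2.27 times that expected from counting error. With nuclear rows rescaled to a common sum, 87.5% instead of 65.4% of the 2-fold rows were higher, and the median difference was 0.99 instead of 0.25. The photosystem median was then -0.16, with 2 of 33 rows lower and 4 higher, and remained at percentile 0 relative to random lists, while the opposite-strand medians were -1.24 for photosystem and 1.92 for heat shock and chaperone genes. A pseudocount of 5 gave medians of 1.28, 1.204 and 0.68 for the small heat shock, HSP100, HSP90 and HSP70, and folding lists.

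The heat differences of the genotypes, which share no library, were set against each other across rows. Rows inside HSP17.4 and LETM2 were among the highest in both genotypes, and rows inside SPL3, a flowering regulator, RRTF1, a redox-responsive transcription factor, and HCF173, needed for photosystem II assembly, were among the lowest in both. The row inside HCF173 had 5615 and 814 FPKM in WT control and heat and 6230 and 753 in miR164OE. That inside LETM2 was listed at 0 in both controls, with 26.7 FPKM in WT heat and 54.8 in miR164OE heat. The size of its difference therefore depends on the pseudocount. Across all 10488 rows Pearson's r was 0.34 and Spearman's rho 0.35. Over the 306 inner rows r was 0.72 and rho 0.73, with 28 rows at least 2-fold higher in both genotypes against 6.17 for independent lists, and 49 lower in both against 18.2. The genotype differences without and with heat, which also share no library, had r = -0.04 over the inner rows and -0.02 over all rows. Under other limits it was 0.18 over inner rows of at least 100 FPKM and -0.18 over the wider rows with at least 80 fragments.

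**Figure D3:**
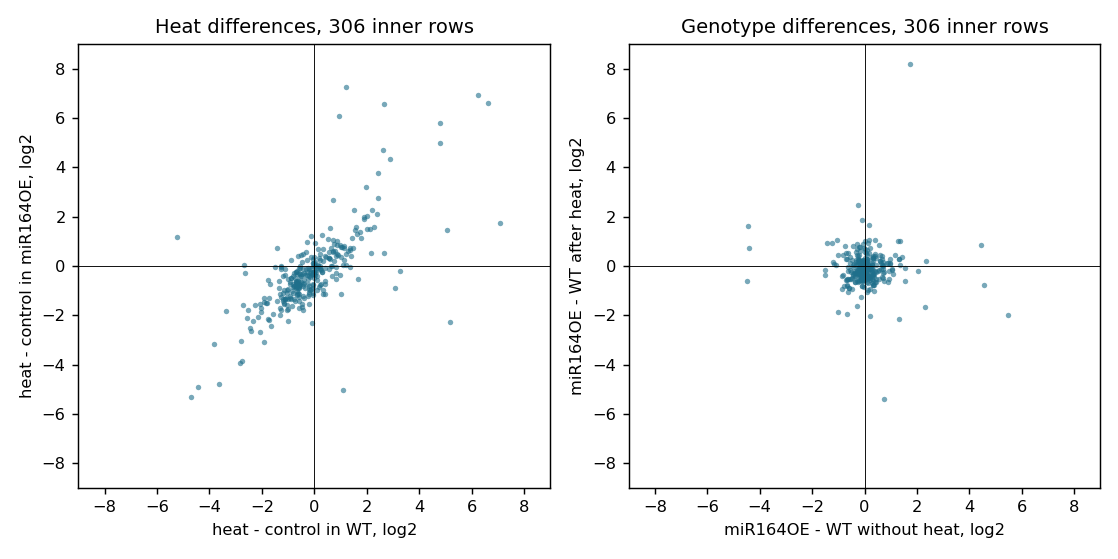
Each point is 1 of 306 rows lying inside a coding gene on the other strand. The left panel plots the heat difference in miR164OE against that in WT (log2 scale, r = 0.72), the right panel the genotype difference after heat against that without heat (log2 scale, r = -0.04).

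Without heat, own rows of the HSP100, HSP90 and HSP70 chaperones were listed lower in miR164OE than in WT in 10 of 21 rows and higher in 1 (median -0.85, percentile 0.555). With a pseudocount of 0.1 the median was -1.65. The list no longer stood apart with a pseudocount of 5 (median -0.31, percentile 3.19) or with a mean of at least 5 FPKM (median -0.65, percentile 8.52, 6 rows). ATJ2, HSP90.2 and ROF1 were listed at 4.69, 3.85 and 3.24 FPKM in WT and at 0 in miR164OE, and cpHSC70-2 differed by -1.82. Over the 4 libraries together ATJ2, HSP90.2 and ROF1 rest on about 18.4, 26.7 and 17.7 fragments. The control libraries hold only a part of these, since each of these rows also had fragments in both heat libraries. The row of AT5G22050, opposite ATJ2 in part, went the other way, with 4.86 FPKM in WT control and 18.8 in miR164OE control. Between these controls the share of own against inner rows was 0.966 times as high in miR164OE by the sums and 0.741 times by the median. Photosystem genes had a median of -0.39 (percentile 0.17), with 2 of 34 rows at least 2-fold lower, PSAL and PSAO, and 1 higher, PSBX, at 1.73. Their 5 members read from the opposite strand had a median of 0.20, inside the central 95% (percentile 95.205), and the 3 with at least 50% of the row opposite them one of 0.088 (percentile 84.855). The 7 heat shock and chaperone genes had a median of -0.09 (percentile 29.6).

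Highest in miR164OE control were the plastid rows PSBK, RPS14, PSAC and PSBE, the small nuclear RNA U2.11 and the mitochondrial row ORF143, all listed at 0 in WT control. Lowest were U5.1b, MT1A, ORF105B, AT7SL-1, BHLH99 and CURT1C, all listed at 0 in miR164OE control. CURT1C, which shapes thylakoid membranes (chromosome 1, 19453435 to 19454765), had 23.3 FPKM in WT control and 8.62 in WT heat and was listed at 0 in both miR164OE libraries. In this comparison 1763 rows were at least 2-fold higher and 1984 lower. Over rows of at least 300 bases, the count of 2-fold rows was 1.51 times that from counting error. Of rows with a mean of at least 20 FPKM, 18.3% differed 2-fold, against 35.7% of all rows. Of the inner rows, 10.8% differed 2-fold, against 38.6% between WT heat and control.

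After heat, the own rows of jasmonate response genes were listed higher in the miR164OE library than in the WT library. The share of own against inner rows was itself 1.22 times as high in miR164OE heat as in WT heat by the sums and 1.38 times by the median. Of 10 measured rows, 5 were at least 2-fold higher and none lower (median 1.02, percentile 99.62). Without a row minimum, over 18 rows, the median was 0.057 and the list no longer stood apart (percentile 91.66), and with a pseudocount of 5 the median was 0.59. VSP2, a storage protein gene induced by jasmonate, had 55.3 FPKM in miR164OE and 7.06 in WT, VSP1 11.005 and 3.54, and JAZ1 and JAZ5, repressors of the pathway, 8.90 and 2.83 in miR164OE while listed at 0 in WT. Over the 4 libraries together VSP2, VSP1, JAZ1 and JAZ5 rest on about 79.2, 22.2, 19.5 and 6.66 fragments. These numbers include fragments of the control libraries, which this comparison does not use. Calvin cycle genes were higher in 5 of 17 rows (median 0.75, percentile 99.91, with medians of 0.37 at a pseudocount of 5 and 0.43 at a mean of at least 5 FPKM), among them GAPA, RBCS1B and FBA1 at 2.104, 1.65 and 1.09, and CP12-2, listed at 0 in WT heat. Photosystem genes were higher in 6 of 34 rows and lower in none (median 0.38, percentile 99.99), with PSBS, PSAH2, LHCB1.4 and PSAL at 1.99, 1.98, 1.47 and 1.45, while the row of ROPGEF11 opposite PSAH2 was at -0.42.

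Read from the opposite strand, the 5 photosystem genes had a median of -0.38 between miR164OE and WT heat, inside the central 95% (percentile 4.14), and the 3 with at least 50% of the row opposite them had a median of -0.38 at percentile 1.955, outside it. The 7 heat shock and chaperone genes had a median of -0.14 (percentile 53.7), and the 4 with at least 50% of the row opposite them one of -0.51, outside the central 95% (percentile 2.375). The row opposite MYC2, a transcription factor of the jasmonate pathway, had 1042 FPKM in miR164OE and 874 in WT. The highest own rows were U5.1b, MIR408, MIR156i, PLS, RPS15 and RPL32A, all listed at 0 in WT heat, with RPL32A, a ribosomal protein gene, at 22.6 FPKM in miR164OE. Lowest were PSBH, RPL16, ATTI6, CURT1C and SEN1, all listed at 0 in miR164OE heat, and the plastid row RPS4, with 74.8 FPKM in WT and 7.28 in miR164OE. In all, 2054 rows were at least 2-fold higher and 1428 lower, and 7.52% of the inner rows differed 2-fold. Over rows of at least 300 bases, the count of 2-fold rows was 1.73 times that from counting error.

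**Figure D4:**
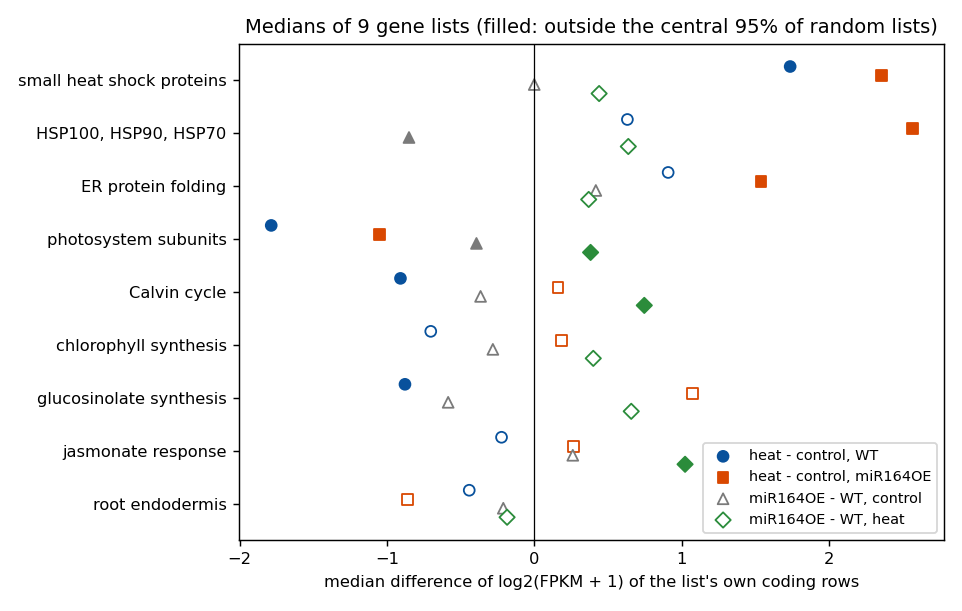
Points are medians of the difference of log2(FPKM + 1) over the coding rows of 9 gene lists (y axis), for the heat differences of both genotypes and the genotype differences without and with heat (x axis, log2 scale). Filled points lie outside the central 95% of random lists; small heat shock proteins are at 1.74 and 2.36 and photosystem subunits at -1.79 and -1.05 for heat in WT and miR164OE.

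The heat response of miR164OE was then compared with that of WT as a difference of differences. HSP100, HSP90 and HSP70 chaperones had larger heat differences in miR164OE in 15 of 21 rows and smaller in none at 2-fold (median 1.42, percentile 99.48). With a pseudocount of 0.1 the median was 2.60, with 15 rows larger and 2 smaller, and with a pseudocount of 5 it was 0.79, with 7 larger and none smaller. For WT heat against control this list had a median of 0.63 (percentile 87, 7 rows higher and 3 lower). Between miR164OE and WT heat its median was 0.64 (percentile 96.24, 3 rows higher and none lower). Both lay inside the central 95%, so the larger difference rests in part on the lower values in miR164OE control (median -0.85). In the difference of heat responses ROF1, ATJ2, HSP90.2 and HSP90.4 were at 4.19, 3.75, 3.20 and 3.04, with at most 6.94, 8.17, 6.94 and 4.6002 FPKM in any library. The photosystem list was at 0.71 (percentile 99.98), with 9 of 34 rows larger and 2 smaller, and the Calvin cycle list at 0.88, with 8 of 17 larger and 1 smaller (percentile 99.0, or 97.145 and inside the central 95% with a mean of at least 5 FPKM), led by PSAH2, PSAL and PSBS at 2.96, 2.68 and 2.59 and by CP12-2, RBCS1B and SBPASE, each listed at 0 in miR164OE control.

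Read from the opposite strand, the 5 photosystem genes had a median of -0.47 (percentile 4.52, and -0.30 after nuclear rescaling), where all 1188 such rows had one of -0.17. The 7 heat shock and chaperone genes had a median of 0.00 (percentile 69.8), with none larger and 3 smaller at 2-fold, and both medians lay inside the central 95%. HSP17.4 was at 0.16, HSFC1 at -1.24 and MBF1C, whose row was listed at 0 in WT control, at -9.87. Over rows with at least 50% of their bases opposite the gene, the median of 4 heat shock genes was -0.62 (percentile 6.37), with 2 smaller, and that of 3 photosystem genes -0.47 (percentile 3.42). Only HOP3 and ATJ2 of those 7 belong to the HSP100, HSP90 and HSP70 list, and they were at 0.65 and -1.78, the row opposite PSAH2 was at -0.63, and no Calvin cycle gene was read in this way. The 5 highest own rows were U5.1b, MT1A, ACP1, MIR156i and CP12-2 and the 5 lowest ATTI6, PSBK, RPS14, PSAC and PSBH, and each was listed at 0 in at least 1 library. At 2-fold, 2905 rows had a larger and 2336 a smaller heat difference in miR164OE. Over rows of at least 300 bases, the count of such rows was 1.36 times that from counting error.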

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

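All tests in this part were chosen after the result was seen, except the thinning of fragments, whose outcome was predicted before it was run.

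Several lists had median heat differences of opposite sign in the genotypes, and several rows were 2-fold higher in 1 and 2-fold lower in the other; with 1 library per group this was not tested. The median heat difference in miR164OE minus that in WT was 1.07 for the Calvin cycle list (-0.91 in WT, 0.16 in miR164OE), 1.11 for antioxidant genes (-0.16 and 0.95), 1.31 for cell cycle genes (-0.08 and 1.23, 3 measured rows) and 1.95 for glucosinolate synthesis (-0.88 and 1.07). Of these 8 medians only those of the Calvin cycle and glucosinolate lists in WT lay outside the central 95% of random lists. Taken gene by gene, the median difference of heat responses was 0.88 for the Calvin cycle (percentile 99.0), 0.29 for antioxidants (68.485), 1.51 for cell cycle (95.52) and 0.98 for glucosinolates (91.46). Over rows with no gene on the other strand it was -0.01 for antioxidants and 1.301 for glucosinolates (percentile 96.81). The minimum gap of 1 for naming a list here was set after the values were seen. Among single rows the heat difference in miR164OE minus that in WT was 19.81 for U5.1b, 7.47 for ACP1, 7.36 for CP12-2 and -8.03 for ATTI6. Each of these 4 was listed at 0 in 2 libraries, so the size of its difference is set by the pseudocount. For rows on the other strand it was 6.42 inside UBQ14, listed at 0 in WT heat, and -7.45 inside PDLP3, listed at 0 in WT control.

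The first pattern weighed is the share of FPKM on rows opposite another gene. Assignment of fragments without regard to strand is argued against, since the row of the coding gene had a median of 0.00703 times the level of the row inside it, where similar levels would be needed. A strand setting reversed when fragments were assigned remains a candidate explanation, since a row would then carry the fragments of the gene opposite to it. Genes of the heat shock and chaperone lists read in that way stood at the 99.71st percentile or above after heat in both genotypes. For the 4 of 7 whose row lies opposite them with at least 50% of its bases, the percentile was 98.84 or above. Own rows of small heat shock proteins also stood at 99.9 and 100 in WT and miR164OE. Those of the HSP100, HSP90 and HSP70 list stood at 87 and 100, and those of heat shock factors at 80.03 and 90.07. This test alone therefore does not separate the strands. A count of 0 among the 100 highest rows, for 34 photosystem and Calvin cycle genes with no gene on the other strand, decides nothing here, because 96 of those 100 rows lie opposite a gene. The best of these 34 genes had a rank of 1130. Own rows of LHCB1.5, PSAG and PSAE1 held at most 178 FPKM in any library. The rows opposite them held 158697, 171972 and 164547 FPKM in WT control. These levels go with a reversed setting but do not exclude antisense transcripts. The heat shock test was moved from the inner rows, where it had 2 members, to the wider set with 7 after medians of both had been seen, antisense transcripts that follow their genes were not tested, and the strand setting was not given in the sources used here.

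The second pattern is that, by their own rows, chaperone, photosystem and Calvin cycle lists had higher heat differences in miR164OE than in WT. A larger estimated number of counted fragments in the miR164OE heat library is argued against as the whole cause. When every library was thinned to the same estimated depth, 100% of the 3 lists stayed above the central 95% of random lists. This holds for the median of 10 thinnings, with the Calvin cycle list ranging from 96.375 to 99.1. A larger share of fragments on the other strand in that library and chance cannot be told apart from an effect of the genotype: own rows against inner rows were 1.22 times as high in miR164OE heat as in WT heat by their sums and 1.38 times by the median (0.966 and 0.741 between the controls, so 1.26 and 1.86 for heat against control), the sums short of and the medians past the bound set for the sums, and without replicates the ratio of lists outside the central 95% in the control comparison to those in this one, 0.667, decides nothing. The opposite-strand readout of 5 photosystem genes, at a median of -0.47, lay inside the central 95% (percentile 4.52). LHCB1.5, LHCB6, PSAE1, PSAG and PSAH2 were all below 0, at -0.40, -0.22, -0.53, -0.47 and -0.63, where the own-row list had 0.71. Between the heat libraries the median was -0.38, inside the central 95% for all 5 (percentile 4.14). It was outside for LHCB1.5, PSAE1 and PSAG (percentile 1.955). The own-row list had 0.38 there. For these 5 genes the readout did not show the higher values of the own-row list. An effect of the overexpressed microRNA stays open and untested.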

How the results depend on the processing

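Settings that depend on the opposite strand, on a mean of at least 20 FPKM, on limits for inner or wider rows or on another worth of 1 fragment were chosen after seeing the data. The others were planned. No list outside the central 95% changed direction under any of the 7 alternatives run for lists. Medians moved by over 1.5 times with the pseudocount in several lists, as given with each. By percentile, the photosystem list kept its side in all 5 comparisons and the small heat shock proteins in both heat comparisons. The number of list medians outside the central 95% was 16 of 115 (13.9%), 15 with nuclear rescaling, 16 with median ratios, 17 with either pseudocount and 18 without a row minimum, 15 of 80 (18.8%) with a mean of at least 5 FPKM and 21 of 100 (21%) without rows opposite a gene. Of the 16, those moving inside were 4 with a mean of at least 5 FPKM (endoplasmic reticulum folding, HSP100, HSP90 and HSP70 chaperones in control, the Calvin cycle difference and glucosinolates), 2 without a row minimum (folding and jasmonate), and 1 each with a pseudocount of 0.1 (folding), a pseudocount of 5 (chaperones in control) and nuclear rescaling (glucosinolates).

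Counts of 2-fold rows moved by more than 1.5 times under several settings, in the order WT heat, miR164OE heat, genotype in control, genotype in heat and difference of heat responses. They were 2636, 2463, 1236, 1221 and 2668 with a pseudocount of 5. With a mean of at least 5 FPKM they were 2359, 2240, 1232, 1060 and 1884, and with a mean of at least 20 FPKM 1123, 1071, 459, 370 and 707. Among rows with no gene on the other strand they were 3204, 3123, 2338, 2151 and 3259. The last 3 settings count fewer rows. Without a row minimum the genotype difference in heat gave 5973 and the difference of heat responses 8964, since more rows were counted. Nuclear rescaling gave 2371 for the genotype in control, and the cause was not tested.

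The correlation of the heat differences of both genotypes was 0.2425 with a pseudocount of 0.1, 0.4501 with a pseudocount of 5, 0.2986 without a row minimum, 0.4445 and 0.4835 with a mean of at least 5 and 20 FPKM, 0.3268 after nuclear rescaling and 0.3312 without rows opposite a gene. The cause of these moves was not tested. Over inner rows it was 0.50 from 200 bases, 0.88 from 600 bases and 0.77 from 100 FPKM. For the wider rows it was 0.49, 0.56 and 0.60 with at least 20, 40 and 80 fragments. Nuclear rescaling turned the split of inner rows from 51 higher and 67 lower to 98 and 28 in WT, and from 37 and 83 to 91 and 23 in miR164OE, so the direction of a typical inner row depends on the scale. The rows read for 5 photosystem genes from the opposite strand stayed lower after heat on that scale, LHCB1.5 by the least, at -0.34 and -0.58. Keeping each row as its own feature gave no value, since no locus code was repeated. Within a comparison, no paired analysis was possible because each group has 1 library, and a fit of heat over both genotypes, with the genotype as block, was not run. Depth limits many rows: 4648 of 10488 (44.3%) were listed at 0 in at least 1 library.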

Other observations

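The test in this part was chosen after the neighbouring values were seen. Of 17 rows beside or over the 8 copies of ONSEN, a heat-activated Copia-type retrotransposon, 6 were at least 16-fold higher after heat in both genotypes. The other 11 were not, and 4 of them were listed at 0 in all libraries, while STP1 had 9.55 FPKM in WT control and was listed at 0 in WT heat. AT1G21940 had 3.997 and 708 FPKM in WT control and heat and 3.92 and 914 in miR164OE. LECRK56 had 1.301 and 294 FPKM in WT and 5.98 and 772 in miR164OE, and AT5G13200 had 2.99 and 483 in WT and 4.50 and 622 in miR164OE. AT1G11270 and AT3G61320 stood at 2.53 and 155 and at 1.52 and 143 FPKM in WT, and AT1G58120 was listed at 0 in both controls with 68.0 FPKM in WT heat and 66.7 in miR164OE heat. Transcription from the retrotransposon may account for these values: of the 8 copies, 6 had an adjacent or overlapping row at least 16-fold higher in both genotypes, against at most 2 in 10000 draws of random gaps between rows. The locus codes of the copies came from background knowledge, and only 72 rows on the nuclear chromosomes passed that bound. All 6 rows are annotated on the strand opposite to the copy, and 4 lie downstream of it. The rows AT1G11280, AT1G21950, AT1G48700, AT1G58150, AT3G32410, AT3G32420 and AT5G13210, which did not pass, are also on the opposite strand. The strand of the fragments themselves is not known, because the strand setting is not given. The copies AT1G48710 and AT3G32415 had no such row, and whether the transcripts begin in the copies was not tested.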
